A study of Mus musculus with 15 samples.

How the data were processed

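The series measured 3 histone marks by ChIP-seq in mouse liver, from 15 samples. The 12 ChIP libraries had region lists, and the 3 input samples had no list of their own and entered only through the authors' calls. Per the series description, nuclei were isolated and chromatin was digested with micrococcal nuclease to mononucleosomes. Groups were taken from the labels. Genotype, mark and, for regeneration, time in hours came from the titles or descriptions. The 2 H3K4me3 libraries of round 2 carried an antibody tag naming H3K9me3 that conflicted with their titles, and were grouped by title. As a check on that choice, 95.8% of the H3K4me3 length of WT replicate 2 and 92.1% of that of KO replicate 2 lay in replicate 1 peaks of the same genotype, and 0.425% to 0.537% lay in H3K9me3 peaks. The labels give replicate 1 no round, and do not say that replicates came from separate animals or how regeneration was started.

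Reads were processed by the authors with Trimmomatic, FastQC 0.11.5, BWA, Picard, MACS2 and SICER, per the submitters' processing notes, which name the builds GRCm38.p4 and mm10. Other versions and settings are not given in the sources used here. Regions were called by the authors per library, not on pooled samples. For H3K4me3 and H3K9me3 the layout of the deposited lists is that of MACS2, with narrow peaks for H3K4me3 and both narrow and broad peaks for H3K9me3. The authors' columns hold a score, a fold enrichment and the −log10 of the p-value and of the q-value of each peak. For H3K27me3 the deposited lists are SICER islands with a window of 1000 bp and a gap of 4000 bp. They give raw ChIP and control read counts per island, deposited without normalization. They also give the p-value, the fold over control scaled by the authors to library size, and the false discovery rate (FDR) as a q-value. The ChIP to control scale was 0.576 and 0.642 in WT replicate 1 and KO, 0.447 at 0 h, and 0.369, 0.342 and 0.438 at 30, 40 and 96 h. Which input served each list is not stated. Islands with identical bounds in WT replicate 1 and KO had equal control counts in 414 of 414 cases, and so did those shared by the 30 and 40 h lists (250 of 250). Of 133 shared by 0 and 30 h, 1 did. The same control library therefore underlies the lists within each of these pairs, and another underlies 0 h.

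Peak folds and scores are the authors' own values. They were used here to describe, rank or filter regions within a list. Between lists they were compared only in ratios of paired islands at 40 and 30 h, and where the text says so. Regions on chromosomes 1 to 19, X and Y were kept. Islands were used at an FDR of 0.01 or below, which left out 417, 604, 625 and 702 islands of the 0, 30, 40 and 96 h lists and none at baseline in WT replicate 1 or KO. Genes came from a RefSeq table of GRCm38.p6, the same build as the lists, with 21887 protein-coding genes on these chromosomes. The table gives gene bounds without strand or transcript starts. The planned window of 1 kb either side of any annotated start was therefore replaced by 1 kb either side of the start-side end of the gene, taken as the end with more H3K4me3 peak length summed over all 4 libraries whatever their genotype. Of the genes, 13984 had 1 such end, 7886 had no peak at either end and 17 were tied, and in those both ends were used. A promoter was marked when at least 1 bp of the window lay in a region. A gene was covered by H3K9me3 when broad peaks held at least 10% of its body, and lost or gained when the other library held none. Outside genes meant more than 5 kb from any protein-coding gene. Neighbouring genes can share an island, so counts of genes are not counts of independent events.

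Gains and losses for each mark were defined before the data were examined, as given in the report, and so were the gene lists, in which 28 of 35 imprinted and 38 of 40 interferon genes were matched to the gene table. Names that are not protein-coding genes were left out. For each list the count was set against 10000 random lists of the same size, drawn from all protein-coding genes or matched on the H3K4me3 call in WT, as a description of these libraries. Genes were named by a rule also fixed beforehand. It took the 10 with the strongest region by the authors' fold for each comparison and direction (the lower fold where several libraries had one), and up to 5 members per fixed list. Symbols starting with Gm and a digit or with LOC, or ending in Rik, were left out. Not every gene chosen by this rule is named in the report. Overlap of H3K9me3 with H3K27me3 was compared with 100 circular shifts of the islands.

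Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and calling code was tested on simulated lists over the real 21887 genes. It gave 500 of 500 windows equal to a base by base count. It found 200 of 200 simulated H3K4me3 losses and 200 of 200 gains, 200 of 200 H3K27me3 losses, and 0 H3K27me3 gains where none was simulated. The simulated libraries were copies of a real list with regions removed, so this checks the code and not the accuracy of calls between real libraries. Simulated genes lay over 20 kb apart, a rule added after a first draw put neighbours with a shared promoter in opposite sets. Of 200 random lists 5 fell below the 5% used to single out lists. Precision is limited by the number of libraries. The exact intervals cover counting error only, and reads were not counted as molecules. Alternatives tried were stricter FDR, q-value or fold limits, equal numbers or lengths of regions, windows of 2.5 kb, a minimum covered part of the window, narrow peaks, other WT replicates and leaving out each library. Left out were regions on other sequences, described in the closing section, and any analysis of base composition, for which no genome sequence was used here.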

Results

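Chromatin carrying H3K4me3, H3K27me3 or H3K9me3 was profiled by ChIP-seq in liver of C57Bl/6 mice aged 8 to 12 weeks. The mice were wild type (WT) or Uhrf1hepKO (KO), in which hepatocytes lack Uhrf1, a gene whose protein directs maintenance methylation of newly replicated DNA. H3K4me3 marks active and poised promoters, H3K27me3 is the mark of Polycomb repression, and H3K9me3 marks silent repeats and some gene clusters. Lists of enriched regions from 12 libraries were compared. H3K4me3 had 2 WT and 2 KO libraries. Replicate 2 of each genotype is labelled as round 2, and replicate 1 carries no round in the labels. H3K27me3 had 2 WT libraries and 1 KO library at baseline, and 1 WT library at each of 30, 40 and 96 h of liver regeneration. WT replicate 2 of H3K27me3 came from the regeneration round, where it was the 0 h point. H3K9me3 had 1 WT and 1 KO library. No p-values are given between groups. The lists hold called regions and no counts per promoter, and the read counts of islands refer to bounds that differ between lists. With 2 H3K4me3 libraries per genotype, exchanging their labels could not give a small p-value, and per-library totals were not tested. H3K9me3 in both genotypes, H3K27me3 in KO and each later time rest on 1 library and have no replicate check. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only.

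The H3K4me3 lists held 72646 and 73875 peaks in replicate 1 of WT and KO and 25952 and 27209 in replicate 2. They covered 45.5 and 44.9 Mb, and 21.4 and 25.3 Mb. ChIP reads in H3K27me3 islands, in units of 1e6, were 16.4 in WT replicate 1, 21.6 in KO and 21.7 in WT at 0 h, against 15.2, 12.8 and 21.4 at 30, 40 and 96 h. The H3K9me3 lists held 56105 broad peaks in WT and 52033 in KO. The total depth of the libraries is unknown, but the ChIP to control scale gives relative depth for H3K27me3 lists that share a control. It was higher in KO (0.642) than in WT replicate 1 (0.576). At 30 and 40 h it was lower (0.369 and 0.342) than at 96 h (0.438). The promoter of Uhrf1 (chromosome 17, 56303337 to 56323486, GRCm38) carried an H3K4me3 peak in all 4 libraries and neither H3K27me3 nor H3K9me3 in any library. A mark at the promoter does not test the deletion, which may lie elsewhere in the gene. Xist, the RNA of the inactive X chromosome, carried none of the 3 marks, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty carried H3K4me3 in all 4 libraries, so each of these 4 libraries held male chromatin.

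The first comparison asked whether loss of Uhrf1 moved H3K4me3 at promoters. Promoters of liver genes were marked alike in both genotypes. All 50 hepatocyte genes, among them Alb and the nuclear receptor gene Ppara, carried H3K4me3 in WT and KO replicate 1, and 48 and 49 of them in replicate 2. Cell cycle and DNA replication genes carried it at 50, 50, 49 and 50 of 50 promoters in WT replicate 1, KO replicate 1, WT replicate 2 and KO replicate 2. Germline genes known to be silenced by DNA methylation stayed mostly without it, with 7 and 7 of 50 marked in replicate 1 of WT and KO, and 3 and 5 in replicate 2. Across 21887 protein-coding genes, 62.3% of promoters were marked in WT and 61.5% in KO in replicate 1, and 54.9% and 57.7% in replicate 2, and 11857 promoters were marked in all 4 libraries.

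A peak in both KO libraries and in neither WT library was found at 31 promoters, and the opposite at 3. Among those gained, Cldn18, a tight junction gene of stomach and lung (chromosome 9, 99690796 to 99717267), had a peak of 8.42-fold enrichment by the authors' own score for the peak, and the nearest WT peak lay 59349 bp from its window. Cd69, an early activation antigen of lymphocytes, and Il2rg, the shared gamma chain of interleukin receptors, each had a fold of 4.47, with the nearest WT peaks 19315 and 4375 bp away. Tmem150b had a fold of 4.71 and no WT peak within 20241 bp. Trim13, which encodes a ubiquitin ligase, had the strongest peak, with a fold of 21.0, but a WT peak ended 11 bp outside its window. WT peaks were likewise close at Ptges, the prostaglandin E synthase gene (119 bp), Nfatc4 (30 bp), Def6 (224 bp), Egfem1 (197 bp) and the receptor gene Cntfr (225 bp), and 21 of the 31 promoters had no WT peak within 1 kb of the window. The 3 promoters lost in KO were those of Bex2, the synaptic gene Nrxn2 and Slc13a2, a citrate transporter gene, each with a fold of 4.38. The nearest KO peaks lay 33313, 14975 and 644 bp from their windows. No gene of the lists fixed beforehand, housekeeping genes, imprinted genes and Zfp genes included, was gained or lost.

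Splits that cross the genotypes gave counts of similar size. WT replicate 1 and KO replicate 2 alone shared 40 promoters, against the 31 gained in KO, while KO replicate 1 and WT replicate 2 alone shared 0, against the 3 lost. Both replicate 1 libraries alone shared 895 promoters. Within replicate 1, KO lacked 374 promoters marked in WT and had 201 that WT lacked. Within replicate 2 the numbers were 46 and 647, so the balance of KO over WT was -173 promoters in replicate 1 and 601 in replicate 2.

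The next comparison asked whether H3K27me3 moved when Uhrf1 was lost. Polycomb targets kept the mark. All 39 Hox genes, which pattern the body axis, lay in islands in both WT libraries and in KO, and so did 96 and 97 of 99 developmental transcription factor genes in WT and 95 in KO (96.0%, interval 90.0 to 98.9). Hepatocyte genes and housekeeping genes carried no island in any of these libraries. Growth factor and receptor genes of regeneration were marked at 22 of 46 promoters in WT replicate 1, 22 in KO and 24 in WT replicate 2. Major urinary protein genes, a cluster of near-identical liver genes on chromosome 4, were marked at 17 of 22 promoters in WT replicate 1, 14 in KO and 9 in WT replicate 2. Reads that fit several Mup copies make those counts uncertain.

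An island present in both WT libraries was absent from KO at 286 promoters, and 206 promoters were marked in KO and in neither WT baseline library. Among the strongest islands lost in KO were those over the X-linked homeobox gene Esx1 (fold 3.197) and the X-linked insulin receptor substrate gene Irs4 (fold 2.70). Others lay over Rnf145, a ubiquitin ligase gene of sterol control (fold 2.75), Tmem59l (2.499), Fbll1 (2.47), Phox2a, a homeobox gene of autonomic neurons (2.44), Ccno, a gene of multiciliated cells (2.36), Gbf1 (2.35) and the potassium channel gene Kcna7 (2.34). Bmi1, which encodes a Polycomb component, was unmarked in KO (WT fold 2.08), as were the bile duct marker Prom1 (2.14), the cyclin gene Ccnd2 (1.78), Reln (1.80), Flt1 (1.76), Bmp4 (1.53) and the homeobox gene Barhl1 (1.69). Of the 50 germline genes, 3 were lost in KO, namely the meiosis genes Mei1 and Hormad2 and Tex19.2, a count that 2.86% of 10000 random lists of this size reached. The histone genes H1f10, H2ac22 and H2bc22 were also lost. Apart from these histone genes and Tex19.2, all lost genes named here were also unmarked in WT liver at 30 and 40 h. Such absence was common at those times: of the 6026 promoters marked at 0 h, 2455 were unmarked at 30 h and 2580 at 40 h. Olfr320, Olfr33 and Olfr550, also lost in KO, were marked at both times. Those times therefore cannot tell whether the absence was particular to KO at baseline.

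The strongest islands gained in KO had lower folds in the KO list than the strongest lost had in the WT lists, which is a comparison between different lists. They included those over Nexmif (fold 2.29), Art4 (2.23), Snx16 (2.06), AI429214 (2.06), Nrap (2.05), Hs1bp3 (2.05), Aars2, which encodes the mitochondrial alanyl tRNA synthetase (2.05), and Commd10 (2.01). Markers of other liver cells were among the genes gained, but Reln of the stellate and fibroblast list and the bile duct marker Prom1 were lost. The endothelial genes Tek (1.37) and Clec4g (1.57) and the stellate and fibroblast genes Dcn (1.55) and Col3a1 (1.33) gave 2 of 16 members in each list, a count reached by 0.96% of random lists. Of 20 lymphocyte markers, Ptprc (1.59) and Gzma (1.81) were gained (1.54% of random lists). The imprinted gene Rtl1 (1.81), Mup14 (1.863) and Cyp2ab1 (1.63) were also gained. Several of these genes were marked in WT liver during regeneration, Gzma and Aars2 at 30, 40 and 96 h and Clec4g, Nexmif, Snx16 and Commd10 at 96 h. Of the 57 clustered protocadherin genes, 5 Pcdha genes were gained, all in 1 island of fold 1.47 on chromosome 18, so that they count as 1 event.

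The numbers that set KO apart lay within or near the range of the WT libraries. WT replicate 1 alone lacked 488 promoters and WT replicate 2 alone 227, against the 286 of KO. WT replicate 1 alone was marked at 211 and WT replicate 2 alone at 1043, against the 206 of KO. Against WT replicate 1, which shared its control library with KO, 497 promoters were lost and 694 gained in KO, so the excess of losses turned into an excess of gains. With islands of a fold of 2 or more in all 3 libraries it also turned, to 175 losses and 269 gains. The excess of losses instead grew at equal covered length, to 410 losses and 166 gains, and against WT replicate 2 alone, to 1329 and 433. Islands covered 417 Mb in WT replicate 1, 483 Mb in WT replicate 2 and 499.9 Mb in KO. The KO total exceeded the WT mean by 49.9 Mb, and the 2 WT libraries differed by 65.1 Mb. The share of island length outside genes was 54.3% in KO, between 55.3% and 52.3% in WT.

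**Figure D1:**
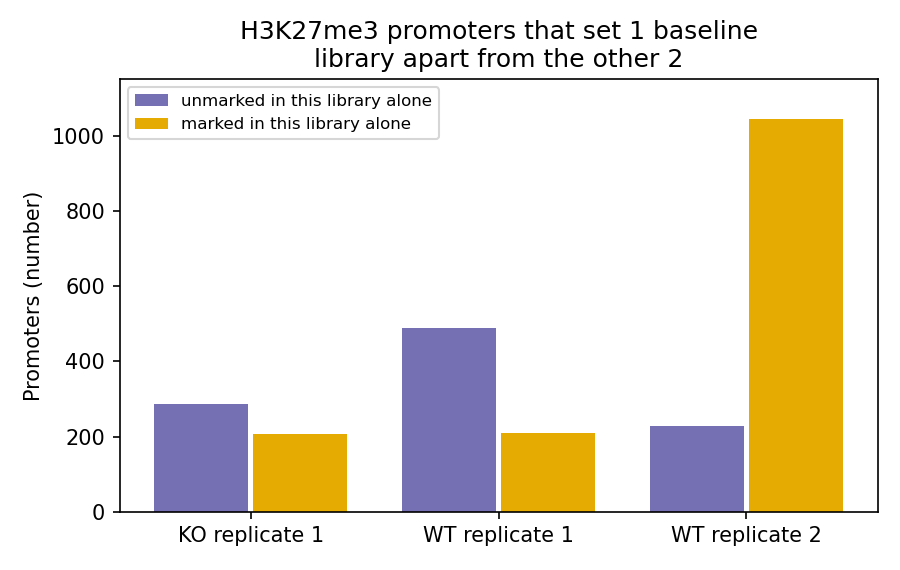
The y axis gives the number of protein-coding promoters that set 1 baseline H3K27me3 library apart from the other 2, for KO replicate 1, WT replicate 1 and WT replicate 2. Bars show promoters unmarked or marked in that library alone, with 286, 488 and 227 promoters unmarked and 206, 211 and 1043 marked in these libraries alone.

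H3K9me3 was compared between 1 WT and 1 KO library of the same round. The number of Zfp genes covered was close in both. Zfp genes, which encode zinc finger proteins, had at least 10% of the gene body in broad peaks at 157 of 367 genes in WT (42.8%, interval 37.7 to 48.0) and 156 in KO (42.5%, interval 37.4 to 47.7). The most covered 1 Mb of the genome in both libraries was chromosome 4 from 147 to 148 Mb, with 647 kb in WT and 623 kb in KO, where 9 of 16 protein-coding genes are Zfp genes. Of the 50 germline genes, 5 were covered in WT and 4 in KO, Tdrd1 (10.5% of the gene in WT and 10.9% in KO) and Tdrd6 (10.2% and 10.9%) among them. Hox, housekeeping and developmental transcription factor genes had 0 members covered in either library.

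Broad peaks covered 57.7 Mb in WT and 49.6 Mb in KO, a difference of -8.03 Mb, and 553 genes were covered in both. Genes covered in WT and free of peaks in KO numbered 31. By the authors' fold the strongest were Rbm24, an RNA-binding protein gene of muscle, Rsl1, which encodes a repressor of sex-limited liver genes, the vomeronasal receptor gene Vmn1r101, the small heat shock protein gene Hspb3 (56.3% of the gene covered in WT), Amd2, the potassium channel gene Kcnj11, Pcdhb20, the glutamate receptor gene Grin3b, Prps1l1 and Zfp579. The neighbouring histone genes H2ac1 and H2bc1 were lost together, with 24.9% and 82.9% of the gene covered in WT and the same peak fold, so that they count as 1 event. Genes covered in KO and free of peaks in WT numbered 15, and included the imprinted gene Zrsr1 (12.3% covered in KO), the spermatid protein gene Tnp1 (38.3%), the protocadherin genes Pcdhb11 and Pcdhb19, Rnase2b, Oxct2b and the pheromone peptide genes Esp31 and Esp34. The lower length in KO depended on weak peaks, since with only peaks at a q-value of 1e-05 or below the difference was 0.261 Mb, with KO higher, and 10 genes were lost and 19 gained.

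Promoters with both H3K4me3 and H3K27me3 numbered 1179 in WT replicate 1 (9.87% of 11942 promoters with H3K4me3 in both WT libraries). In KO they numbered 1414 (11.4% of 12380), and 980 were shared. The combination is found at poised developmental genes. Here the marks came from separate libraries of liver, and the median island length was 28000 bp in WT replicate 1 and 26000 bp in KO. A call of both marks therefore does not place them in the same cells or on the same nucleosomes. Endothelial markers had both marks at 3 of 16 promoters in WT and 7 in KO, stellate and fibroblast markers at 6 and 7 of 16, growth factor and receptor genes at 12 and 11 of 46, Hox genes at 9 and 11 of 39, and Mup genes at 15 and 10 of 22. Interferon response genes had both at 5 of 38 promoters in each genotype, and chromatin regulator genes at 2 of 40 in WT and 1 in KO. With WT replicate 2 in place of replicate 1 the WT count was 1581 and the difference changed sign, from 235 promoters more in KO to -167. The Mup count in WT then fell from 15 to 7, below the 10 of KO, the endothelial count rose from 3 to 5, the growth factor and receptor count from 12 to 13, the stellate count from 6 to 7 and the interferon count from 5 to 6, and the Hox count stayed at 9.

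H3K27me3 and H3K9me3 occupied largely separate parts of the genome. Of the H3K9me3 length, 9.21% lay in H3K27me3 islands in WT replicate 1 and 9.94% in KO. Islands shifted along each chromosome 100 times gave 16.3% on average in WT (range 15.0 to 17.95) and 19.6% in KO (range 18.2 to 21.7), so both observed shares lay below every shifted one. The difference of 0.735 percentage points between genotypes became -1.89 with WT replicate 2 and -0.109 with islands of equal covered length.

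The regeneration series asked how H3K27me3 changed in WT liver over time. The 39 Hox promoters were all marked at 0 and 96 h, against 12 at 30 h (30.8%, interval 17.0 to 47.6) and 21 at 40 h (53.8%, interval 37.2 to 69.9). Developmental transcription factor genes, of which part are Hox genes, were marked at 97 of 99 promoters at 0 h, 50 at 30 h (50.5%, interval 40.3 to 60.7), 66 at 40 h (66.7%, interval 56.5 to 75.8) and 97 at 96 h. Growth factor and receptor genes were marked at 24 of 46 promoters at 0 and 96 h and 13 at 30 and 40 h, and bile duct markers at 10 of 15 at 0 and 96 h against 3 at 30 h and 6 at 40 h. Over all genes 27.5%, 17.99%, 17.6% and 25.03% of promoters were marked at 0, 30, 40 and 96 h. The 0 h islands were called with another control library than the islands at the 3 later times, which shared one.

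**Figure D2:**
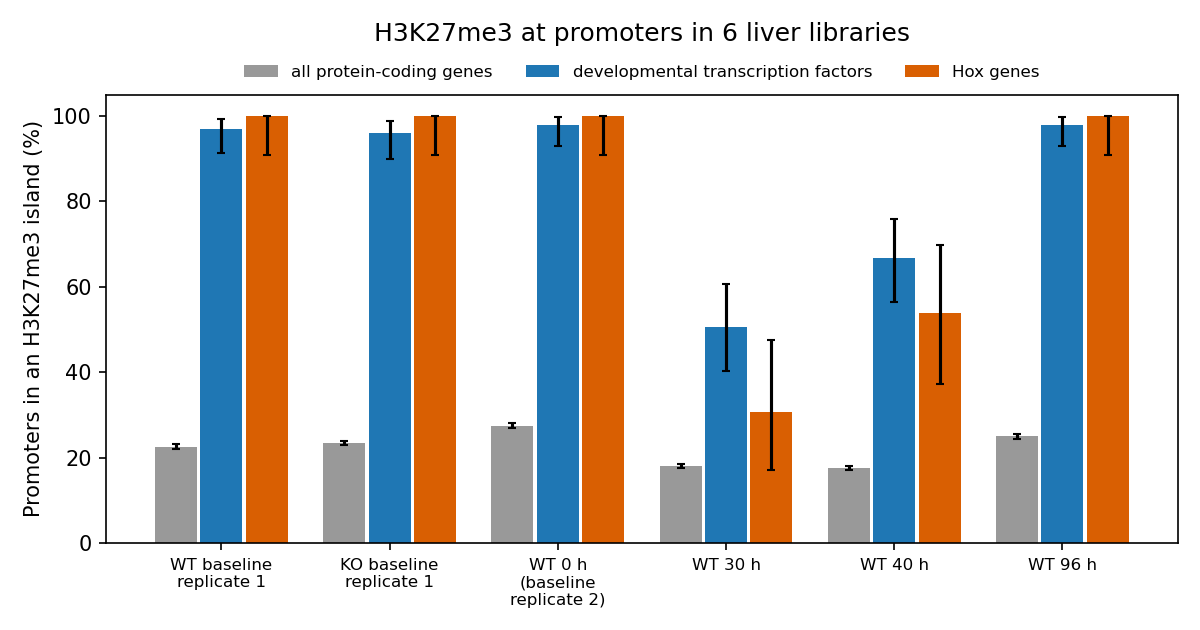
The y axis gives the percentage of promoters in an H3K27me3 island in each of 6 libraries, for all protein-coding genes, 99 developmental transcription factor genes and 39 Hox genes, with exact 95% intervals as error bars. Hox genes fell to 30.8% at 30 h and 53.8% at 40 h and stood at 39 of 39 genes in the other 4 libraries.

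The HoxA cluster on chromosome 6 lay in 1 island from 52032001 to 52381000 at 0 h (fold 2.62) and from 52032001 to 52348000 at 96 h (fold 3.27). At 40 h an island from 52214001 to 52247000 (fold 2.09) covered the part from Hoxa7 to Hoxa11. A class defined after the values were seen, marked at 0 and 96 h and unmarked at 30 and 40 h, held 1026 of the 4883 promoters marked at both 0 and 96 h (21.0%, interval 19.9 to 22.2). It held 15 of 39 Hox genes (38.5%, interval 23.4 to 55.4) and 18 of the 74 other developmental genes marked at both times (24.3%, interval 15.1 to 35.7), against 20.8% of promoters in neither list. At 30 h alone 69.2% of these Hox promoters were unmarked (interval 52.4 to 82.98), against 41.9% (30.5 to 53.9) of the other developmental genes and 31.7% (30.4 to 33.1) of promoters in neither list. At 40 h these shares were 46.2% (30.1 to 62.8), 29.7% and 34.7%. Hox genes share islands within clusters, so their intervals are too narrow. With islands of a fold of 2 or more, 99.1% of the 788 promoters marked at 0 and 96 h were unmarked at 30 h, and 67 developmental and 33 Hox genes fell in the class, so that limit does not separate the lists. Tbx2, Cdx2 and Zic1, chosen from that class as regulators of limb, gut and neural development, had folds of 2.14, 2.41 and 2.38 at 0 h and 3.76, 2.27 and 3.13 at 96 h. The opposite class, marked at 30 and 40 h alone, held 66 promoters.

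**Figure D3:**
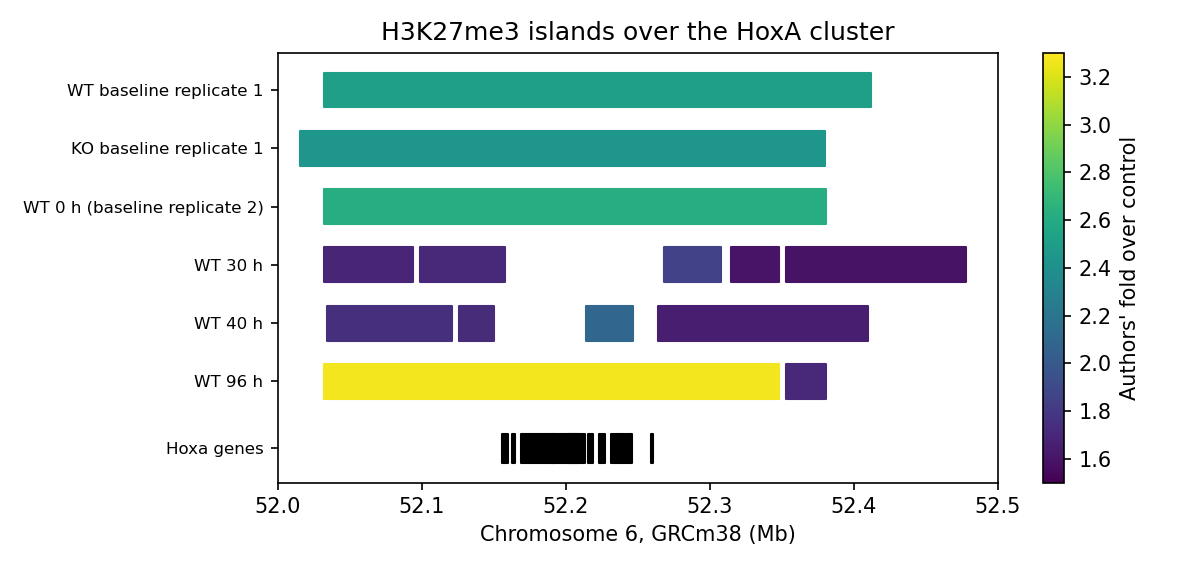
Bars are H3K27me3 islands along chromosome 6 (x axis, Mb, GRCm38) in 6 libraries (y axis), coloured by the authors' fold over control, above the 11 Hoxa genes in black. A single island covers the cluster at baseline in WT and KO and at 96 h, and gaps lie over most of the genes at 30 and 40 h.

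Promoters marked at 0 h and at none of the later times numbered 752. The strongest were Rhou, a small GTPase gene (fold 3.35), Ccdc106 and its neighbour U2af2, which encodes a splicing factor (3.28), the calcium channel genes Cacng6 and Cacng8 (3.26), the potassium channel gene Kcnn1 (3.21), Pdpn (2.90), Rnf145 (2.75), Ptprd (2.71) and Calcoco1 (2.70). Stress and priming genes among them were Gadd45b (2.11) and Atf3 (1.93), 2 of 35 in that list. Of the cell cycle genes Bub1 (1.75) and Ccnd1, the cyclin of hepatocyte entry into the cycle (1.34), were lost, and the Ccnd1 island was found in the 0 h library alone of all 6. The list of p53 targets, cycle inhibitors and apoptosis genes lost 4 of 30, namely Bcl2, Cdkn1c, Ccng1 and Bcl2l1 (1.82% of random lists). Of 18 macrophage and neutrophil markers, Spi1, Csf1r and Itgam were lost (2.37% of random lists). Other members lost were the imprinted genes Peg10 and Sgce, Tgfb1, the endothelial gene Cdh5, the lymphocyte genes Lck and Cd79b, Oas1a of the interferon response and the stellate cell gene Cygb. Of the genes named here Cacng6, Cacng8, Pdpn, Rnf145, Bub1, Bcl2 and Oas1a were also marked in WT replicate 1, and the others were called lost from the 0 h library alone of the pair of WT baseline libraries.

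An island at each later time and none at 0 h was found at 98 promoters, each weak by the lowest of its folds. The strongest were Bcl2l14 (lowest fold 1.64), Zfp955a (1.60), Aars2 (1.60), the macrophage gene Siglec1 (1.57), the growth factor gene Fgf7 (1.55), Tspan8 (1.55), Timm21 (1.505), Vmn1r184 (1.49), the cytokine gene Il5 (1.48) and Jakmip2 (1.47). Of 1106 olfactory receptor genes 12 were gained, a count reached by 0.28% of random lists but by 29.5% of lists matched on H3K4me3, and of 353 vomeronasal receptor genes 5 were gained (2.11% and 21.5%). Gzma, Sycp1 and Pcdha12 were also gained. None of the 98 remained with a fold of 2 or more. That limit also left 99.1% of the 788 promoters marked at 0 and 96 h unmarked at 30 h, so it cannot judge these gains in particular. Of the 752 losses 127 were also marked in WT replicate 1, and of the 98 gains 31 were unmarked there. Of the gains named here Zfp955a, Fgf7, Tspan8, Vmn1r184, Jakmip2 and Sycp1 were already marked in WT replicate 1.

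**Figure D4:**
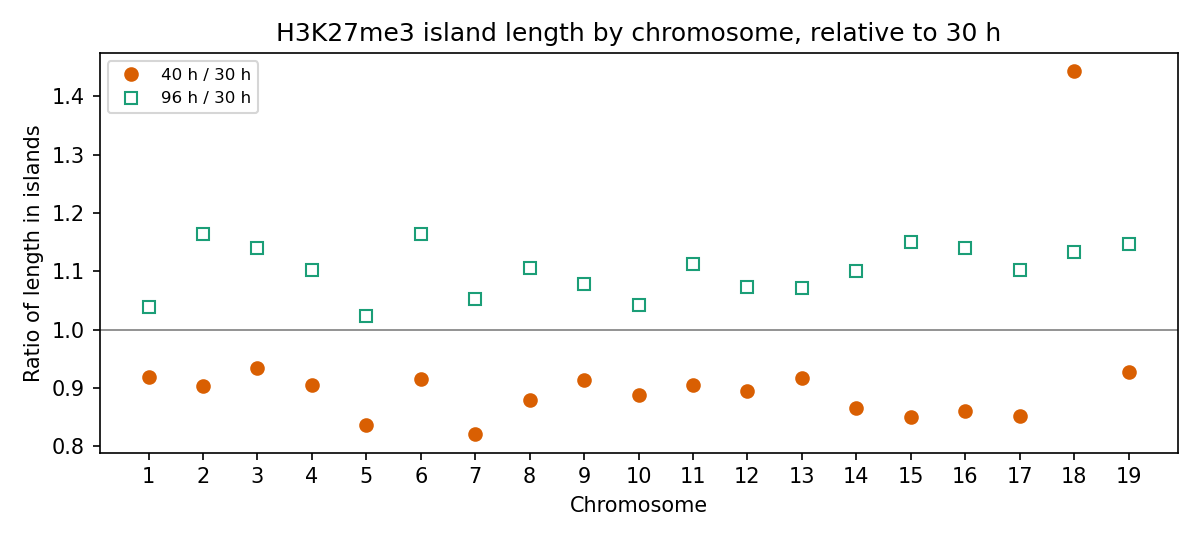
Points give the ratio of H3K27me3 island length on each of 19 autosomes (x axis) between 40 and 30 h and between 96 and 30 h (y axis, no unit, line at 1). At 40 h chromosome 18 stood at 1.44 and the other 18 autosomes between 0.820 and 0.935.

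Chromosome 18 departed from the other autosomes in the 40 h library. Islands covered 19.9 Mb of it at 40 h, against 15.0, 13.8 and 15.6 Mb at 0, 30 and 96 h. The 40 h length was 1.44 times that at 30 h, and 0.820 to 0.935 times on the other 18 autosomes. The clustered protocadherin genes, which lie on this chromosome, were marked at 41 of 57 promoters at 40 h, against 37, 26 and 26 at 0, 30 and 96 h.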

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

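The tests of explanations in this part were chosen after the results were seen, and the limit of a fold of 2 had been planned for covered length but not for the class marked at 0 and 96 h alone. The bounds of both tests of covered length were made stricter after their values were seen. Regions outside the chromosomes used in the comparisons appeared in several lists. On an unplaced scaffold, H3K4me3 had 20 and 57 peaks in WT replicates 1 and 2 and 26 and 48 in KO, and H3K9me3 had 79 narrow peaks in WT and 78 in KO. The mitochondrial genome carried an H3K27me3 island in WT replicate 1 (fold 1.26) and in KO (fold 1.04), 11 and 6 H3K4me3 peaks in replicate 1 of WT and KO, and 5 broad and 2 narrow H3K9me3 peaks in WT. Mitochondrial DNA carries no histones, and the cause was not tested. Groups held too few libraries to look for a sample far from its group.

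H3K27me3 was absent from 1026 promoters at 30 and 40 h that were marked at 0 and 96 h, 21.0% of those marked at both times, and at 30 h Hox promoters stood out (69.2% unmarked) but the other developmental genes did not clearly (41.9%, interval 30.5 to 53.9, against 31.7%, 30.4 to 33.1), while with a fold of 2 or more the class held 67 developmental and 33 Hox genes because 99.1% of all promoters then fell out at 30 h. That general drop in fold goes with weaker enrichment at 30 h. Compared between lists, the median island fold was 1.45 at 30 and 40 h, against 1.58 at 0 h and 1.56 at 96 h. A true loss of the mark could lower it as well. Depth was also lower, with a ChIP to control scale of 0.369 at 30 h against 0.438 at 96 h, but the folds are already scaled to library size. The loss among the 603 weakest promoters at 0 h goes with weaker enrichment too. Of these 50.4% (interval 46.3 to 54.5) stayed marked at 30 h. As the whole cause, weaker enrichment would not be expected to take more of the 603 strongest than of the middle. Of the strongest 48.1% (44.0 to 52.2) stayed, against 63.7% (60.9 to 66.5) of the 1205 in the middle. Promoters can share an island, so these intervals are too narrow. At 96 h the strongest kept the mark most often, at 90.5%. In KO they kept it about as often as the middle (81.3% against 81.9%), and in WT replicate 1 more often (83.7% against 77.5%). The other control library behind the 0 h islands is argued against by 96 h, where 97.98% of the developmental genes were marked with the control used at 30 and 40 h. Lower recovery of CpG-rich DNA remains open, as 46.3% of promoters with H3K4me3 stayed marked at 30 h and 70.6% of those without. These shares were 80.4% and 81.6% at 96 h, 73.6% and 75.4% in WT replicate 1, and 74.0% and 81.4% in KO. Genes without H3K4me3 at either end were scored at both ends and most others at 1, so the 2 shares are not measured alike. A true loss of the mark at promoters with H3K4me3 could give the difference as well, and no sequence was used to separate them. A passing loss of H3K27me3 in regenerating liver is the biological candidate explanation, untested because each time had 1 library.

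Islands covered more of the genome in KO than in either WT library, by 82.4 and 17.3 Mb. The 2 WT libraries differed by 65.1 Mb, more than the 49.9 Mb between KO and the WT mean but less than the 82.4 Mb between KO and the WT library that shared its control. They also differed in control library, so variation between libraries and an effect of Uhrf1 loss cannot be told apart with 1 KO library. Depth differed as well, with a ChIP to control scale of 0.642 in KO and 0.576 in WT replicate 1, and its part was not tested. A part for weak islands stays open as well, since a fold of 2 or more left 3.12 Mb but shortened every library, and the ratio of KO to the WT mean went from 1.11 to 1.05.

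Chromosome 18 was covered 1.44 times as much at 40 h as at 30 h. More DNA of this chromosome in the 40 h library, from a gain in part of the cells, could raise every island on it, and islands paired between both times had a median 40 h to 30 h fold ratio of 1.03 (1.01 to 1.04) there, above the range of 0.990 to 1.01 on the other autosomes. The length was higher in 18 of 19 bins of 5 Mb, along nearly the whole chromosome. The ratio was 1.04 in the weaker islands, where the other autosomes reached 1.03, and 1.01 in the stronger, where they reached 1.002, so the margin was small, and a spread of the mark along the chromosome would give the same, so the explanations cannot be told apart without read depth along the chromosome. The 40 h group had 1 library, and no biological explanation was tested.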

How the results depend on the processing

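Of 129 alternatives, 68 were planned before the data were examined and the other 61 were chosen after seeing them. No paired test was run, since the calls come from no test to which a pairing could be added. The counts within each H3K4me3 replicate number are given beside the joint ones, with KO minus WT differences of -173 and 601 promoters. The planned use of transcript starts alone was not run, for want of strand. A count was kept when it changed by a factor of 1.5 or less. A difference was kept when it changed by less than the standard deviation of the 2 WT libraries, and reversed when its sign changed. That spread was 46.0 Mb for H3K27me3 length, so wide changes still counted as kept. H3K9me3 length had no such spread, so any change counted as moved or reversed. Of the alternatives planned 39 kept the result, 22 moved it and 7 reversed it. The added ones kept 39, moved 21 and reversed 1. The cause was not tested except where fewer libraries or peaks make it plain. Leaving out libraries loosened the calls by construction. H3K4me3 gains then ranged from 52 to 647 and losses from 7 to 374, against 31 and 3. Without WT replicate 1, WT replicate 2, KO replicate 1 or KO replicate 2 the gains were 502, 52, 136 and 180 and the losses 7, 291, 42 and 46, and without both libraries of replicate 2 the gains were 201. H3K27me3 gains in KO ranged from 433 (without WT replicate 1) to 694 (without WT replicate 2) and losses from 497 (without WT replicate 2) to 1329 (without WT replicate 1), regeneration gains from 164 (without 96 h) to 182 (without 30 h; 177 without 40 h) and losses from 884 to 1778 (without 96 h), the class marked at 0 and 96 h alone from 1571 (without 40 h) to 1696 (without 30 h), its developmental genes from 30 to 46 and its Hox genes from 18 to 27. H3K4me3 losses were 10 with equal numbers of peaks and 6 with windows of 2.5 kb. With a fold of 2 or more, H3K27me3 losses in KO were 175 and gains 269, regeneration gains 0, and the developmental and Hox genes of that class 67 and 33. With either gene end the developmental count was 16. From WT replicate 1 as the start, regeneration gains were 153 and losses 272. The KO minus WT share outside genes (0.467 points) reversed to -0.665 with a fold of 2 or more, -0.735 at equal length, -0.551 for gene bodies alone and -1.02 without WT replicate 2, and rose to 1.950 without WT replicate 1. The KO excess of covered length fell to 3.12 Mb with a fold of 2 or more, where KO covered 62.9 Mb. The H3K9me3 length difference was -2.52 Mb with narrow peaks, -6.47 Mb with equal numbers and 0.261 Mb, reversed, at a q-value of 1e-05. H3K9me3 gene losses and gains were 11 and 7 with narrow peaks, 5 and 1 at 50% of the gene, and 144 and 137 in promoter windows, and losses were 10 and gains 19 at that q-value. With WT replicate 2 the promoters with both marks reversed to -167 and the H3K9me3 overlap to -1.89 points, and the overlap to -0.109 at equal length. Of 55 list counts above 0, 12 were reached by under 5% of random lists and 10 with matched lists, counting neighbours that share a region as separate genes. Counts of 0 were left out and can never fall under 5%, so 12 of 55 overstates the share over all lists and directions examined. The percentages of single lists carry no correction for how many lists and directions were examined. Read depth outside islands is unknown, so weak regions limit every count.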

Other observations

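The tests of this part were written before their results were seen, except that the label rule of the H3K4me3 test was made stricter afterwards. Olfactory receptor promoters lay in H3K27me3 islands at 203 of 1106 genes in WT replicate 1, 189 in KO and 196 in WT replicate 2, and cytochrome P450 promoters at 23, 21 and 21 of 99. Imprinted genes were marked at 11, 12 and 13 of 28 promoters. Rpl10l, a retrogene expressed in testis and chosen after its values were seen, had 48.4% of its length in H3K9me3 peaks in WT and 78.8% in KO, and Peg10, an imprinted retroelement-derived gene chosen likewise, had 9.79% and 3.67%. Protocadherin genes of the clustered families were covered at 18 of 57 in WT and 11 in KO.

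A hypothesis was that H3K27me3 moves onto bases that lost H3K9me3 in KO. H3K9me3 was present in WT alone over 21.7 Mb. KO islands covered 10.0045% of it, and WT islands 9.84% in replicate 1 and 12.1% in replicate 2. The KO share was not above the higher WT share, so the prediction was not met. The order was the same over bases with H3K9me3 in both genotypes, at 8.99% for KO and 8.83% and 11.7% for WT. The result was therefore not particular to bases that lost H3K9me3, and it cannot decide on such a move.

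Another hypothesis was that H3K4me3 appears outside genes in KO. Of 248 regions with a peak in both KO libraries and no WT library, 34.3% (interval 28.4 to 40.5) lay outside genes, above the 15.6% (11.2 to 20.9) of the 231 regions shared by WT replicate 1 and KO replicate 2 alone. The 45 regions of both WT libraries alone gave 28.9% (16.4 to 44.3), and the 29 shared by KO replicate 1 and WT replicate 2 alone gave 62.1% (42.3 to 79.3). The excess over one crossed pair met the prediction, but the WT interval overlaps that of KO and the other crossed pair lies higher, so a gain outside genes may exist and cannot be told apart from differences between the libraries.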
